A study of Mus musculus with 24 samples.

How the data were processed

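Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, that were either wild type (WT) or labelled as lacking c-Jun, a transcription factor subunit of the AP-1 family. The 24 arrays fall into 8 groups of 3, 1 group for each of 2 genotypes and 4 treatments. Per the labels' protocols, cells were left to adhere for 24 h and then kept for 3 h in fresh medium alone, with interferon gamma (IFNg, 1000 IU/mL), with cycloheximide (CHX, an inhibitor of protein synthesis), or with both. The labels number the arrays of each group 1 to 3 and do not say whether these came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

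The deposited values are log2 expression values that the authors made with robust multi-array averaging (RMA), which corrects background, normalizes between arrays and summarises the probes of a transcript. RMA and the mouse build mm9 are named in the submitters' processing notes, and the aroma package for R and limma are named in the series' design text. Versions, array annotation and filters are not given in the sources used here. The arrays are Affymetrix Mouse Exon ST arrays. Since normalization between arrays brings their distributions closer, a change shared by most genes cannot be measured reliably. The distributions still differed. Array medians ran from 6.79 to 7.00, and no 2 arrays held identical values. Interquartile ranges ran from 2.62 (WT control numbered 1) to 3.75 (WT IFNg+CHX numbered 3). The number of arrays limits the precision.

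The table has 17831 rows. A platform annotation table paired 15620 rows with 1 gene symbol, 1370 with several, and listed no gene for 841; the last 2 kinds, 2211 rows, were left out of the comparisons. Symbols were updated through Entrez identifiers with a RefSeq table of assembly GRCm38, which held 15559 of the 15620 rows. Where a gene had more than 1 row (375 genes), the row with the highest mean over all 24 arrays was used, which left 15224 genes. No coordinates are given, since the reference table and the authors' build differ. Genes such as Stat1 had no row that named them alone.

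Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) to all 24 arrays with 1 mean per group, so that all groups share the estimate of the spread. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the 15224 genes of a comparison, and the threshold was an adjusted p of 0.05. Unless another fit is named, every adjusted p comes from this fit. Fold changes are differences of log2 means with their standard errors (SE). On data simulated for IFNg+CHX against control in WT cells (15224 genes, 200 of them changed, 5 simulations), this fit recovered 54.4% of changes of 1 log2 unit and 96.4% of changes of 2, and a fit with the replicate number as a block within genotype recovered 95.6% and 100%. Over the 5 simulations the fit without a block called 1 unchanged gene, and 0 in a contrast with no change, and the blocked fit called 33 and 1. The simulated arrays were given the replicate effects and the spread of the blocked fit. The higher recovery with the block was therefore built in and does not test whether the numbers pair the arrays.

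The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison of 2 groups, the 10 largest rises and 10 largest falls past the threshold whose 3 arrays of one group all lay above the 3 of the other, and for each difference between effects the 5 largest in each direction. It passed over predicted and multigene symbols. It also took up to 4 members of each list. Lists were 17 gene groups for interferon, cytokine, AP-1, stress, sterol, matrix and cell cycle genes, and 8 lists of markers of other cell types and of sex-linked genes. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Overlaps between gene sets that share no array were tested with a one-sided Fisher's exact test.

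Whether the replicate numbers pair the arrays was checked from the correlation, across genes, of the deviations of same-numbered arrays from their group means. For each WT comparison all 3 correlations were over 0.1 (0.35 to 0.90). In the c-Jun null arrays they were over 0.1 for IFNg against control (0.47 to 0.75) and IFNg+CHX against CHX (0.62 to 0.78), but not for IFNg+CHX against control (number 2, -0.10) or CHX against control (number 2, -0.04), nor between genotypes (number 2, -0.15). The pairing comes from these data and not from the labels. A fit with a replicate block within genotype was therefore added after seeing the data, and its values stand beside the 6 paired comparisons. It called 110 genes for WT IFNg+CHX against control, where the fit without a block called 12. The same rule for naming genes was applied to it.

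Other alternatives were quantile normalization, a shift to one median, removal of the dimmest 40% of genes, every row of the table and the mean of a gene's rows. Further ones were only the arrays compared, an intensity trend, a block shared by both genotypes and each array left out in turn. An adjusted p under 0.01 for overlaps and a plain t-test per gene for IFNg+CHX against control were also used. The series' design text names limma, so the plain t-test is not the test named there. A fit without the 4 c-Jun null arrays numbered 2 was added after seeing the data, for the reason given with the Jun values.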

Results

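Expression of 15224 genes was compared between wild-type (WT) and c-Jun null mouse embryonic fibroblasts left untreated or treated for 3 h with interferon gamma (IFNg), cycloheximide (CHX) or both, with 3 arrays in each of 8 groups. IFNg is a cytokine that signals through the transcription factor STAT1. Per the series' design text, CHX was added to limit secondary responses that need new protein, and the combined treatment against untreated cells was the comparison meant to list direct STAT1 targets. Stat1 itself had no row that named it alone and is not reported.

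Jun was measured first, as a check of the labels. Its signal was not lost in the arrays labelled c-Jun null: the mean was 9.21 ± 0.53 (SD, n = 3) on the log2 scale in WT control arrays and 8.86 ± 1.03 (n = 3) in c-Jun null control arrays. Where the probes lie relative to the deleted part is not known here, so the value does not test the genotype label. In WT, Jun lay at 11.02 ± 0.19 (n = 3) after CHX and 11.12 ± 0.19 (n = 3) after IFNg+CHX. In the c-Jun null arrays numbered 1 and 3 it was also higher with CHX (10.17 and 9.82) than in the controls (8.75 and 7.88), whereas in those numbered 2 it was 8.29 with CHX and 9.93 in the control. Fos, another AP-1 subunit, went the same way, with 7.93 in the CHX array numbered 2 and 11.23 in the control numbered 2, against 10.91 and 11.37 with CHX and 7.81 in both controls for numbers 1 and 3. Because of this, counts without the 4 c-Jun null arrays numbered 2 are given where they moved by over 1.5 times.

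**Figure D1:**
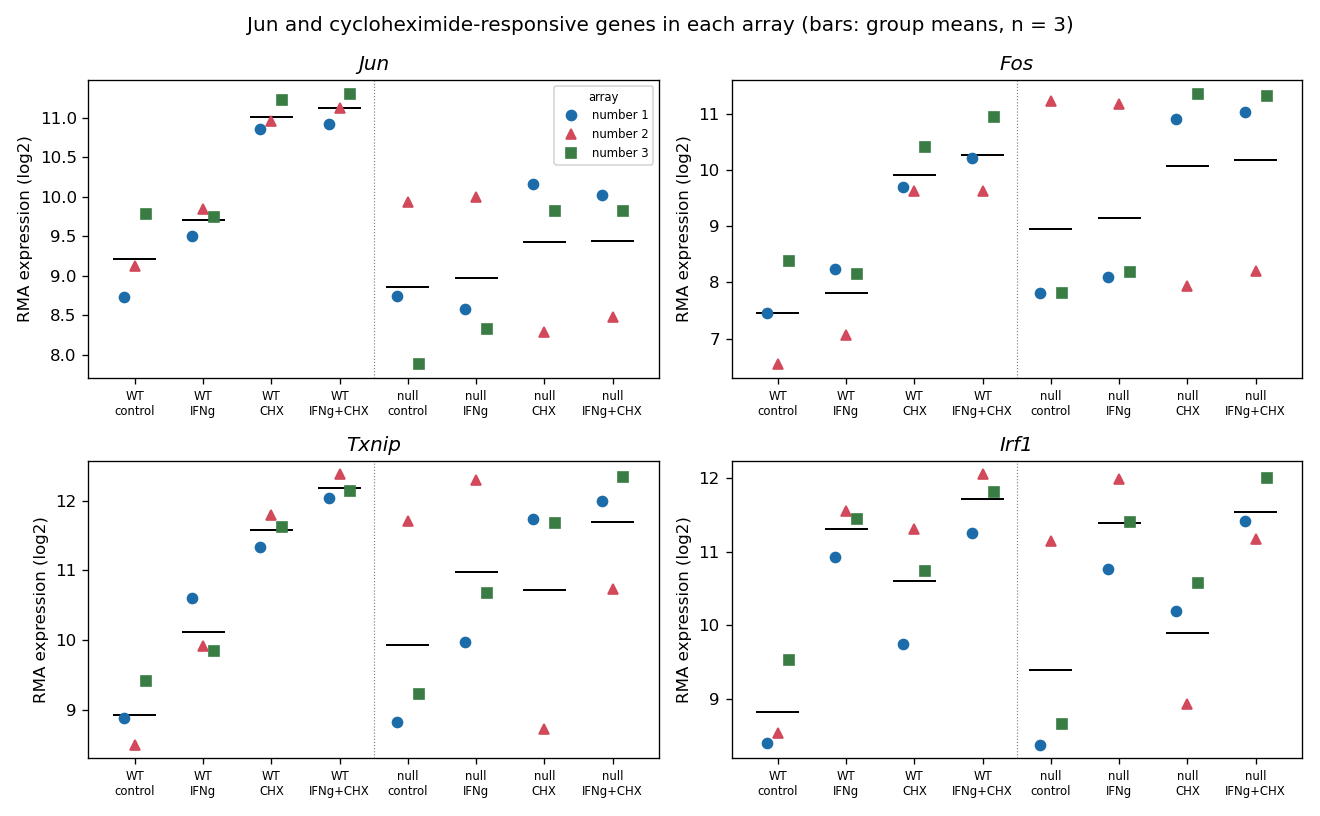
Expression of Jun, Fos, Txnip and Irf1 (vertical axes, RMA values on the log2 scale) in each of 24 arrays by group (horizontal axis), with symbols for the replicate number and bars for group means. In the c-Jun null control and CHX arrays numbered 2, Fos lies at 11.23 and 7.93, the other way round from numbers 1 and 3.

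The genotype comparison asks how untreated c-Jun null cells differ from untreated WT cells. The labels give 1 source per genotype, so the loss of c-Jun cannot be told apart from other differences between the lines. Antiviral genes of the interferon response were at a lower level in the c-Jun null arrays. Rsad2, which encodes the antiviral protein viperin, was 46.4-fold lower (log2 -5.54, SE 0.25, limma adjusted p = 1.2e-12), at 5.58 ± 0.21 (SD, n = 3) against 11.12 ± 0.42 (n = 3). Oasl1 (log2 -5.32), Ifit1 (-5.30), Oas2 (-3.92) and the chemokines Ccl5 (-5.10) and Cxcl10 (-3.95) were lower as well. Of the 20 measured genes of the type I interferon antiviral list, 16 were lower and none higher, with a median of -2.47 (camera adjusted p = 3.3e-16, and adjusted p = 0.171 with an estimated correlation; 18 were lower when adjusted over the list alone). Ifnb1, which encodes interferon beta, did not pass the test (log2 -0.22, adjusted p = 0.654). Of 9 interferon-induced GTPases, 7 were lower, among them Gvin1 (-3.97), Gbp7 (-3.93) and Gbp3 (-3.79), with a camera adjusted p = 8.7e-07 and adjusted p = 0.213 with an estimated correlation. Of 21 interferon signalling genes, 10 were lower, with Irf7 (-4.50), Trim25 (-4.19) and Stat2 (-2.88), and 3 were higher (camera adjusted p = 0.0049, and adjusted p = 0.448 with an estimated correlation).

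**Figure D2:**
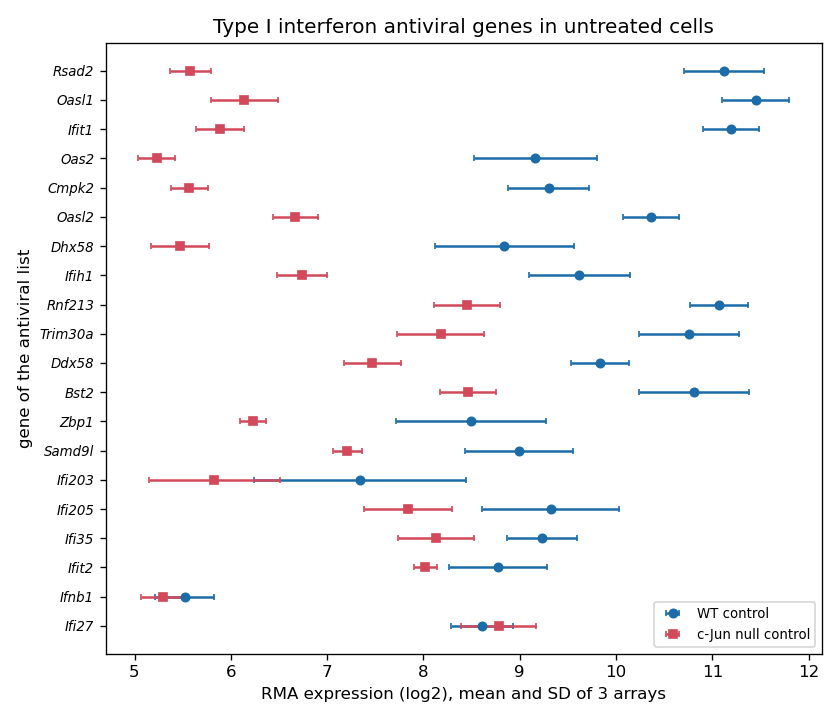
Mean and SD (n = 3) of the 20 measured genes of the type I interferon antiviral list in untreated WT (circles) and c-Jun null (squares) arrays; the horizontal axis is the RMA value on the log2 scale and each line of the vertical axis is a gene. Rsad2 lies at 11.12 in WT and 5.58 in c-Jun null controls, and the SD bars of Ifi27 and Ifnb1 overlap between the genotypes.

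Among genes higher in untreated c-Jun null cells, the largest differences were in F5 (coagulation factor V; log2 6.35, SE 0.22, adjusted p = 3.0e-14), Aldh1a1, a retinaldehyde dehydrogenase (5.58), Pdpn, which encodes podoplanin (5.53), C1qtnf3 (5.41) and Igfbp2, an insulin-like growth factor binding protein (5.21). Srpx2, Abca9, the Wnt antagonist Sfrp1, Ckb and the glucose transporter gene Slc2a3 followed, at 4.81 to 5.14. Lower were Pdlim1 (-5.30), the cathepsin gene Ctsz (-5.19), Il13ra1 (-5.14), the caveolin gene Cav1 (-4.94), the glutamine transporter gene Slc1a5 (-4.92) and Cxcl5 (-4.86). The order of these genes is not settled, since background was not measured here and the lower group was often dim. Mean WT levels of F5 (4.74), Aldh1a1 (4.97), C1qtnf3 (5.14) and Abca9 (4.92) lay below the lower quartile of every WT control array, and the c-Jun null level of Il13ra1 (4.76) below that of every c-Jun null control array. In all, 2076 genes were higher and 1517 lower in c-Jun null controls, 1019 and 732 of them by at least 2-fold. These values and those of the lists include the c-Jun null control numbered 2, where Fos lay at 11.23 against 7.81 in the others. Without the 4 c-Jun null arrays numbered 2, 1649 genes were higher and 1073 lower, 976 and 632 of them by at least 2-fold. The replicate numbers did not pair arrays across the genotypes.

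Other lists held genes that differed between the untreated genotypes, and none of these lists passed camera with an estimated correlation. Of 16 cholesterol synthesis genes, 14 were lower and none higher, such as Idi1 (-2.30), Fdps (-2.16) and Fdft1 (-1.73), with a camera adjusted p = 1.8e-07 (adjusted p = 0.401 with an estimated correlation). Of 19 p53 target genes, 9 were higher and 1 lower, with Trp53inp1 (3.27), Perp (2.99), Ccng1 (2.50) and the cell cycle inhibitor gene Cdkn1a (2.43); the camera adjusted p = 5.4e-05 rose to adjusted p = 0.213 with an estimated correlation. Of 32 matrix and fibroblast genes, 11 were lower and 3 higher, led by the collagen gene Col1a2 (-4.80) and the mesenchymal marker Thy1 (-3.31), with camera adjusted p = 0.273; the list's median was 0.11 and its mean -0.52. Of 26 chemokine and cytokine genes, 9 were lower and 1 higher (camera adjusted p = 0.0124, and adjusted p = 0.705 with an estimated correlation). Of 15 NF-kB feedback genes, 4 were lower and none higher, led by Birc3 at -2.81 (camera adjusted p = 0.0262, and adjusted p = 0.686 with an estimated correlation). Of 24 S phase genes 3 were lower (camera adjusted p = 0.0042, and adjusted p = 0.74 with an estimated correlation), and of 23 G2/M genes 2 were lower (0.0149, and adjusted p = 0.74 with an estimated correlation), with no member of either list higher.

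The other lists did not pass camera between the untreated genotypes, apart from neural and glial markers. Of 13 genes of MHC class I presentation, 5 were lower, led by the immunoproteasome gene Psmb8 (-2.14) and the peptide transporter gene Tap1 (-1.19), and of 5 MHC class II genes 1 was higher, Cd74 at 1.43 (camera adjusted p = 0.0999 and 0.613). Of 14 AP-1 family genes, Maff (1.25) and Mafk (0.81) were higher and Fosl1 (-2.36) lower (0.346). Of 40 immediate early genes, 7 were higher, such as Pim1 (2.20), and 5 lower, such as Zfp36 (-2.56), with 0.147. Of 17 reported AP-1 targets, 2 were higher and 4 lower, led by Plau, which encodes urokinase, at -3.70 (0.213). Of 21 stress response genes, 3 were higher and 3 lower (0.962), and of 10 snoRNA host and decay-sensitive genes 3 were lower, led by Gas5 at -3.07 (0.0999).

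Markers of other cell types were measured as well. Of 7 neural and glial markers, 4 were higher in the c-Jun null controls, led by Sox2 at 1.98 (camera adjusted p = 0.0296, and adjusted p = 0.315 with an estimated correlation). Among 11 macrophage markers Cd14 was lower (-2.19), among 9 endothelial markers Kdr was higher (1.06), and among 10 epithelial markers Krt19 was lower (-2.52). Among 8 skeletal muscle markers Des was higher (1.55), and among 6 bone and cartilage markers Col2a1 was higher (0.78). None of 6 adipocyte markers passed limma's test after adjustment, and none of these lists passed camera (adjusted p 0.147 to 0.992). The measured sex-linked genes, Eif2s3y (-3.14) and Kdm5d (-2.32), both Y-linked, were lower in the c-Jun null controls. The list counts adjusted over the list alone differed from those over all genes for the antiviral list, as given above, and for interferon signalling (4 higher and 12 lower), GTPases (8 lower), NF-kB feedback (5 lower), matrix (7 higher and 11 lower), stress response (4 and 4), cholesterol synthesis (15 lower), and S phase and G2/M (0 each).

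IFNg alone was compared with no treatment in each genotype. In WT cells it raised Cxcl9, which encodes a chemokine that attracts T cells, 7.44-fold (log2 2.90, SE 0.40, adjusted p = 0.0034), from 5.37 ± 0.23 (SD, n = 3) to 8.26 ± 0.55 (n = 3), and Cd274, which encodes the immune checkpoint ligand PD-L1, 6.02-fold (log2 2.59, SE 0.33, adjusted p = 0.00183). Cells labelled c-Jun null showed rises in the interferon-induced GTPase gene Tgtp1 (7.68-fold, log2 2.94, SE 0.39, adjusted p = 0.00164), Irf8 (2.05, adjusted p = 8.1e-04) and Irf9, a partner of STAT proteins (1.60, adjusted p = 0.0193). These 2 and 3 genes were the ones called. With the replicate block within genotype, 24 genes rose and 2 fell in WT, and 10 rose in c-Jun null. In that fit 5 and 10 lists passed camera where 3 and 4 did without a block. The WT rises then included the signalling inhibitor gene Socs3 (2.73, blocked adjusted p = 3.0e-04), Cxcl11 (2.08), Cish (1.54) and Tgtp1 (1.52), and the falls were Defb5 (-1.19) and Gp9 (-0.73). Both falls were in dim genes. Defb5 (4.47 in controls, 3.28 with IFNg) lay below the lower quartile of every array compared. Gp9 lay near it in controls (5.57) and below it with IFNg (4.84). The c-Jun null rises then included Socs3 (2.07, blocked adjusted p = 0.00962), the GTPase gene Irgm1 (1.85), Stat2 (1.52), Gbp7 (1.33) and Tap1 (1.13). Without the 4 c-Jun null arrays numbered 2, a fit added after seeing the data, 4 genes rose in WT and 0 passed limma's test in c-Jun null. In c-Jun null 128 lay at an unadjusted p under 0.05, where 761 are expected by chance. There Tgtp1, Irf8 and Irf9 had 3.02, 1.81 and 1.57, with adjusted p = 0.133, 0.133 and 0.256. Leaving out these arrays and adding the block gave 7 genes in c-Jun null, these 3 among them. With only the arrays compared, c-Jun null gave 0. Leaving out the WT IFNg array numbered 3 left 1 gene in WT.

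Of the 21 interferon signalling genes, none passed the all-gene test with IFNg in WT and 6 rose when adjusted over the list alone (median 0.48, camera adjusted p = 1.6e-21, and adjusted p = 0.00241 with an estimated correlation). The c-Jun null arrays showed 2 rises, and 8 adjusted over the list alone (median 0.39, camera adjusted p = 3.7e-27, and adjusted p = 6.8e-04 with an estimated correlation). For the 9 GTPases, the WT median was 0.66 with 0 members past the test and 2 adjusted over the list alone (camera adjusted p = 9.7e-12, and adjusted p = 0.0551 with an estimated correlation, or 0.0028 in the fit with the replicate block within genotype, where 3 members rose). The c-Jun null GTPase median was 0.50 with 1 member past the test and 3 adjusted over the list alone (camera adjusted p = 5.0e-16, and adjusted p = 0.0164 with an estimated correlation, or 0.463 without the 4 arrays numbered 2). Listed GTPases whose row names several genes are not among the 9. Over every row of the table, a row of Iigp1, Gm4951 and F830016B08Rik rose in WT with IFNg and with IFNg+CHX against control. A row of Igtp and Irgm2 rose in c-Jun null with IFNg, and with IFNg+CHX against control and against CHX.

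**Figure D3:**
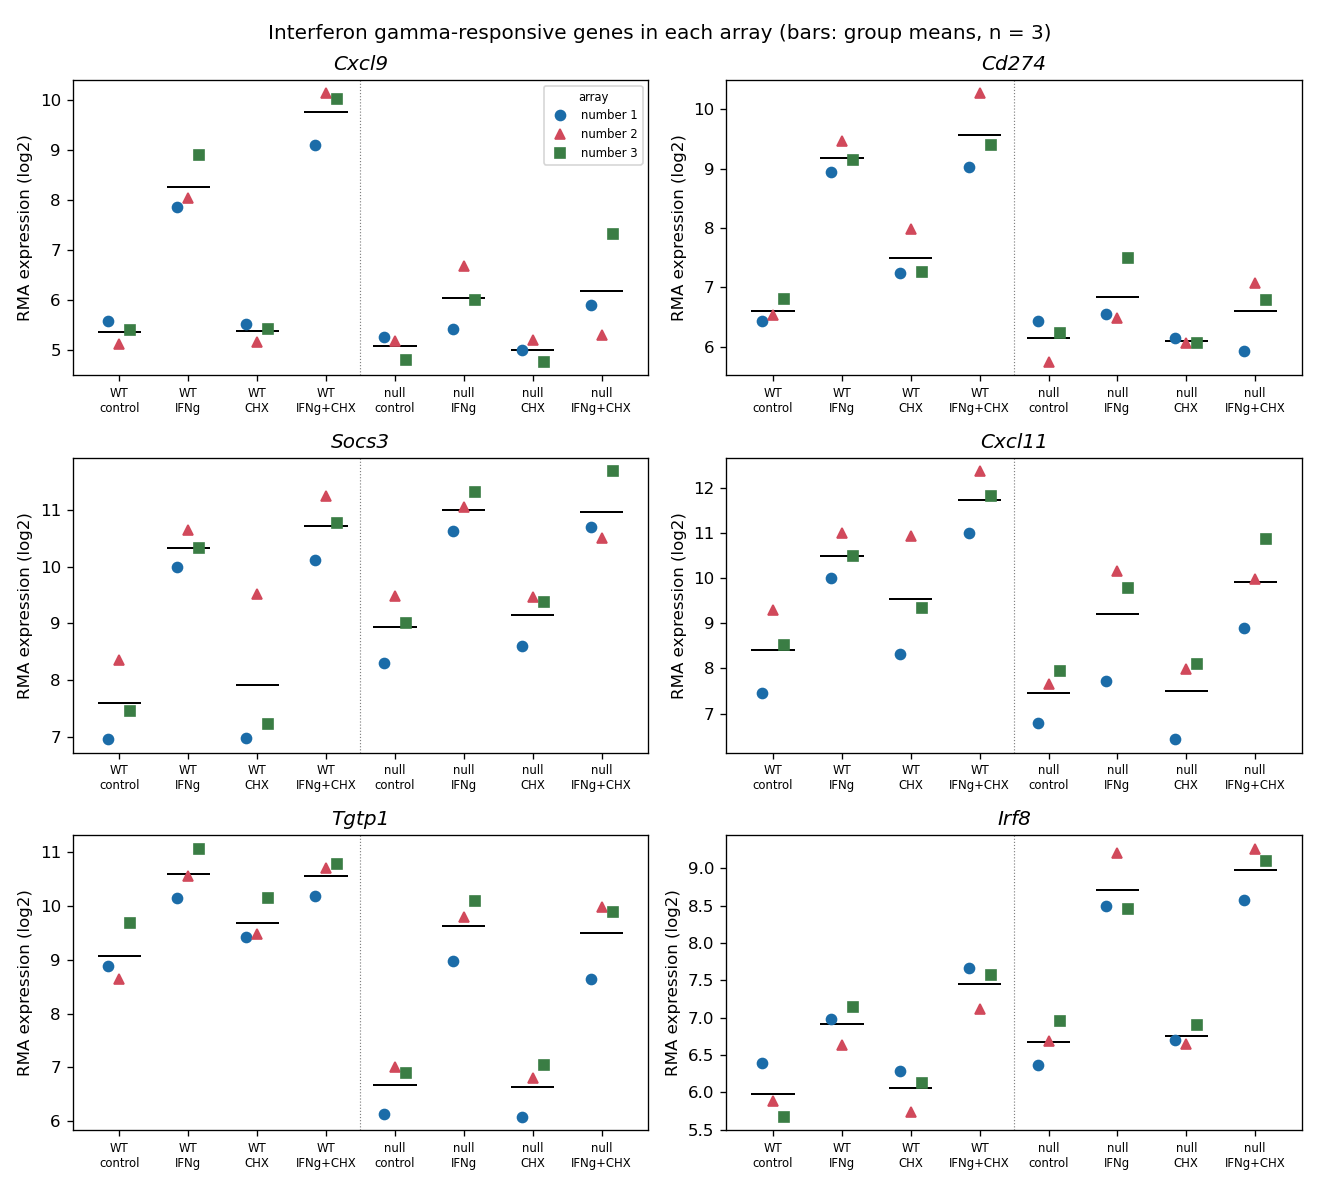
Expression of Cxcl9, Cd274, Socs3, Cxcl11, Tgtp1 and Irf8 (vertical axes, RMA values on the log2 scale) in each of 24 arrays by group (horizontal axis), with symbols for the replicate number and bars for group means. Cxcl9 lies at 9.75 on average in WT arrays with IFNg+CHX and at 5.37 in WT controls.

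CHX alone was compared with no treatment, as the background of the combined treatment. In WT cells it raised Mx2, an interferon-induced GTPase gene, 6.98-fold (log2 2.80, SE 0.35, adjusted p = 0.00131), from 7.21 ± 0.58 (SD, n = 3) to 10.01 ± 0.57 (n = 3), Zfp36, whose product promotes decay of cytokine mRNAs (1.86, adjusted p = 0.0124), and the linker histone gene H1f2 (1.52, adjusted p = 0.0124). No other gene was called. The fit with the replicate block within genotype gave 11 rises in WT, among them Mx1 (1.12, blocked adjusted p = 0.00285), Oas1b (1.23) and Hoxa5 (0.59). Of 15 NF-kB feedback genes in WT, 0 passed over all genes and 7 adjusted over the list alone (median 0.75, camera adjusted p = 6.2e-25, and adjusted p = 0.00547 with an estimated correlation). Of 40 immediate early genes, 1 rose, and 8 adjusted over the list alone (median 0.70, camera adjusted p = 5.4e-35, and adjusted p = 0.0318 with an estimated correlation, or 0.119 with the block). Of 9 GTPases, 1 rose, and 2 adjusted over the list alone (median 0.42, camera adjusted p = 4.9e-09, and adjusted p = 0.0654 with an estimated correlation, or 0.00802 with the block). Of 26 chemokine and cytokine genes, 0 passed either way (median 0.28, camera adjusted p = 8.6e-10, and adjusted p = 0.151 with an estimated correlation, or 0.00802 with the block). Leaving out the WT control array numbered 1 or 2, or the WT CHX array numbered 3, left 1 gene.

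Among c-Jun null arrays, no gene passed limma's test for CHX alone (55 genes at an unadjusted p under 0.05, where 761 are expected by chance). Without the 4 arrays numbered 2, Fos (log2 3.33, SE 0.52, adjusted p = 0.0311), Txnip, which encodes a thioredoxin inhibitor (2.68, adjusted p = 0.00217), Ier2 (2.60, adjusted p = 4.0e-04) and Rasl11b (1.72, adjusted p = 0.0284) rose. With the block within genotype as well, 68 genes rose and 7 fell, although 2 pairs are too few to check whether the numbers pair these arrays. Of the 40 immediate early genes, 0 passed with all arrays (median 0.30, camera adjusted p = 3.3e-09, and adjusted p = 0.587 with an estimated correlation). Without the 4 arrays 2 rose, and 19 adjusted over the list alone (median 0.93, camera adjusted p = 4.1e-60, and adjusted p = 4.4e-04 with an estimated correlation). In that fit WT showed 15 rises, among them Txnip (2.65), Fos (2.46), Dusp1 (1.91), Ier2 (1.89) and Jun (1.80, adjusted p = 0.00627). The WT differences were the same with all arrays, since the 4 arrays enter the WT tests only through the shared spread. Without them the SE fell from 1.01 to 0.42 for Fos and from 0.73 to 0.26 for Txnip, and rose from 0.28 to 0.30 for Zfp36. The genes of the fit without the 4 arrays were chosen by the same rule with 1 exception. In comparisons with c-Jun null arrays, the arrays of one group did not have to lie above those of the other.

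The combined treatment against no treatment is the comparison the design text names for STAT1 targets. In WT cells Cxcl9 rose 20.9-fold (log2 4.38, SE 0.40, adjusted p = 7.5e-06), from 5.37 ± 0.23 (SD, n = 3) to 9.75 ± 0.57 (n = 3). Mx2 (3.19), Socs3 (3.12), Cd274 (2.97), Zfp36 (2.32), the signalling inhibitor gene Cish (2.13), Trim6 (1.74), H1f2 (1.52), Tmem140 (1.48) and Irf8 (1.47) rose as well, with adjusted p from 6.7e-05 to 0.0137. In all 12 genes rose and 0 fell by limma's test. At an unadjusted p under 0.05 there were 418 genes, fewer than the 761 expected by chance. This shortfall means that the test without a block may call too few genes. Under the replicate block within genotype 104 rose and 6 fell, with 1526 at an unadjusted p under 0.05. Those rises included Cxcl11 (3.31, blocked adjusted p = 4.7e-06), Irf1, a transcription factor gene of the interferon response (2.90, 0.0113), Il6 (2.50, 0.00566), Rnd3 (2.49, 4.3e-04) and Tnfaip3 (2.46, 0.0408), and the falls included Ube2d2b (-0.96), Aprt (-0.59) and Eif1a (-0.54). Ube2d2b was dim, near the lower quartile of the arrays in controls (5.35) and below it with IFNg+CHX (4.39). Of the genes called without a block, Mx2, Zfp36 and H1f2 were also called for CHX alone. Of the 104 blocked rises, 91.35% also lay above 0 with CHX alone (median 0.42), against 36.04% of all genes. These 2 comparisons share the control arrays. With CHX alone Tnfaip3 differed by 2.61 (blocked limma adjusted p = 0.151), and mean Irf1 was 10.60 against 8.82 in controls. A rise against control thus does not by itself separate IFNg from CHX. Without a block the count of 12 became 6 with only the arrays compared and 34 without the 4 c-Jun null arrays numbered 2. It was 7 without the WT control array numbered 2, and 20 and 6 without the WT IFNg+CHX arrays numbered 1 and 3.

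IFNg+CHX in c-Jun null cells raised Tgtp1 7.08-fold (log2 2.82, SE 0.39, adjusted p = 0.00304), from 6.68 ± 0.48 (SD, n = 3) to 9.50 ± 0.74 (n = 3), Irf8 (2.31, adjusted p = 1.1e-04) and Irf9 (1.76, adjusted p = 0.00521), the 3 genes called. Without the 4 arrays numbered 2, 8 genes rose, among them Fos (3.37, adjusted p = 0.0199), Irf1 (3.20, adjusted p = 0.0125), Txnip (3.14, adjusted p = 5.1e-04), Ier2 (2.32, adjusted p = 9.3e-04), Irf8 (2.17) and Irf9 (1.88), whereas Tgtp1 had 2.75 with adjusted p = 0.0678. With the block within genotype as well, 82 genes rose and 15 fell. Leaving out the c-Jun null control array numbered 1 or the IFNg+CHX array numbered 3 left 1 gene.

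Among lists, 3 of the 21 interferon signalling genes rose with IFNg+CHX in WT, and 8 adjusted over the list alone (median 0.58, camera adjusted p = 1.7e-27, and adjusted p = 6.3e-04 with an estimated correlation). The c-Jun null arrays had 2 rises, and 10 adjusted over the list alone (median 0.36, camera adjusted p = 7.2e-37, and adjusted p = 1.1e-04 with an estimated correlation). Of 9 GTPases 1 rose in each genotype, with 5 in WT and 3 in c-Jun null adjusted over the list alone (camera adjusted p = 6.4e-21 and 2.8e-22, and adjusted p = 0.00517 and 0.00368 with an estimated correlation). The latter was 0.101 without the 4 arrays numbered 2. In WT, the NF-kB feedback list had a median of 0.54 with 0 members past the test and 5 adjusted over the list alone (camera adjusted p = 8.2e-17, and adjusted p = 0.012 with an estimated correlation, or 0.0688 with the block). For the immediate early list the WT median was 0.71, with 1 member past the test and 10 adjusted over the list alone (camera adjusted p = 2.8e-25, and adjusted p = 0.0412 with an estimated correlation, or 0.201 with the block). For 14 AP-1 family genes it was 0.35, with 0 past the test and 2 adjusted over the list alone (camera adjusted p = 2.2e-07, and adjusted p = 0.0392 with an estimated correlation, or 0.201 with the block). The antiviral list (median 0.55, 0 members either way, camera adjusted p = 4.9e-11) and the chemokine list (median 0.47, 1 member and 3 adjusted over the list alone, camera adjusted p = 8.8e-09) had adjusted p = 0.103 and 0.179 with an estimated correlation, and 0.0119 and 0.0116 with the block. For the immediate early list in c-Jun null cells the median was 0.20, with 0 members either way (camera adjusted p = 0.00377, and adjusted p = 0.816 with an estimated correlation, or 0.00429 without the 4 arrays).

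IFNg+CHX against CHX gives the IFNg effect with CHX on both sides. In WT cells Cxcl9 rose 20.8-fold (log2 4.38, SE 0.40, adjusted p = 7.8e-06), from 5.37 ± 0.19 (SD, n = 3) to 9.75 ± 0.57 (n = 3), and Cd274 (2.07, adjusted p = 0.0168) and Cish (1.84, adjusted p = 0.01) rose too. Among c-Jun null arrays Tgtp1 (2.86, SE 0.39, adjusted p = 0.00251) and Irf8 (2.23, adjusted p = 2.1e-04) rose. Fitting the replicate block within genotype gave 28 rises in WT and 13 in c-Jun null, where 7 lists passed camera against 3 without it. The WT rises then included Socs3 (2.80, blocked adjusted p = 2.9e-04), Cxcl11 (2.20), the activin antagonist gene Fst (1.45) and Irf8 (1.40). The c-Jun null rises then included Cxcl11 (2.41, blocked adjusted p = 2.6e-04), Cxcl10 (1.92), Irgm1 (1.83), Socs3 (1.81), Irf9 (1.33) and Cish (1.17). Of the interferon signalling genes 1 rose in each genotype, with 4 in WT and 8 in c-Jun null adjusted over the list alone (camera adjusted p = 9.3e-24 and 9.2e-22, and adjusted p = 0.00142 and 0.00227 with an estimated correlation). Of 9 GTPases, 0 rose in WT (median 0.55, 0 adjusted over the list alone, camera adjusted p = 4.8e-12, and adjusted p = 0.0502 with an estimated correlation, or 9.3e-04 with the block) and 1 in c-Jun null, 3 adjusted over the list alone (camera adjusted p = 2.5e-13, and adjusted p = 0.0343 with an estimated correlation, or 0.154 without the 4 arrays). The count in WT was 6 without the IFNg+CHX array numbered 1 and 1 without any of the IFNg+CHX arrays numbered 2 and 3 or the CHX arrays numbered 1 and 3. In c-Jun null it was 1 without the 4 arrays numbered 2, where Tgtp1 had 2.70 with adjusted p = 0.454.

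Whether effects differed between genotypes was tested as a difference of differences. With 1 source per genotype, these differences may come from the lines rather than from c-Jun. The effect of IFNg+CHX was lower in c-Jun null than in WT cells for Cxcl9 (difference -3.30 on the log2 scale, SE 0.56, adjusted p = 0.0478), Zfp36 (-2.49, SE 0.40, adjusted p = 0.0436) and Trim6 (-1.84, SE 0.30, adjusted p = 0.0436). In c-Jun null arrays Trim6 was dim in controls (4.40) and with IFNg+CHX (4.31), below the lower quartile of each of these arrays, and Zfp36 lay near it (5.39 and 5.22). Cxcl9 was dim in c-Jun null controls (5.09, below the lower quartile of each) and lay at 6.17 with IFNg+CHX. These 3 calls were lost without the 4 c-Jun null arrays numbered 2 (adjusted p = 0.492, 0.149 and 0.149), with differences of -2.81, -2.71 and -1.96. With the block within genotype, although the numbers do not pair the c-Jun null arrays of this effect, 11 genes passed, these 3 among them (adjusted p = 0.0354, 0.00545 and 0.00545). With both changes 6 passed, 2 of the 3 among them. Without a block the count was 0 or 1 without any single array of the 4 groups except the WT IFNg+CHX array numbered 1. By limma without a block no gene passed for the genotype difference in the IFNg effect (173 at an unadjusted p under 0.05). Nor did any pass for that in the CHX effect (62) or in the IFNg effect under CHX (100). The difference CHX made to the IFNg effect had none in WT (50) or c-Jun null cells (40). Each of these unadjusted counts lay below the 761 expected by chance. The numbers pair the arrays for the IFNg effect with and without CHX, and with the block the effect was higher in c-Jun null cells for Irf9 (2.83-fold, blocked adjusted p = 0.0403) and Tgtp1 (2.67-fold, 0.0403) with IFNg, and for Tgtp1 under CHX (3.97-fold, 8.3e-04). Irf9 went from 7.18 to 8.78 with IFNg in c-Jun null and from 9.78 to 9.88 in WT arrays, and Tgtp1 from 6.68 to 9.62 and from 9.06 to 10.59. For the IFNg effect, the block shared by both genotypes called 0 genes, and without a block and without the 4 arrays both genes had adjusted p = 0.901. The NF-kB feedback list had a smaller CHX effect in c-Jun null cells (median -0.74, camera adjusted p = 8.7e-18, and adjusted p = 0.0244 with an estimated correlation, or 0.47 without the 4 arrays), with no member past the test. With IFNg+CHX, the immediate early list differed by a median of -0.45 (camera adjusted p = 1.2e-11, and adjusted p = 0.557 with an estimated correlation).

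Overlaps between calls were counted among the 15224 genes. Lists from the same fit share each gene's estimate of the spread even where they share no array, and genes can change together. The exact test assumes neither, so its p-values may be too small. Using the replicate block within genotype, 6 genes rose with IFNg in both WT (24) and c-Jun null cells (10), where 0.0158 are expected of independent lists (one-sided Fisher's exact test, p = 1.6e-15): Irgm1, Tgtp1, Socs3, Cxcl11, Trim21 and Irf8. Without a block 0 of the 2 and 3 genes were shared. Within WT, 14 genes were raised by IFNg both without (24) and with CHX (28), where 0.0441 are expected (Fisher's exact test, p = 1.9e-34), and within c-Jun null cells 9 (10 and 13, 0.00854 expected, p = 5.9e-29). Without a block these were 2 (2 and 3) and 2 (3 and 2). In both genotypes, by the same exact test, 6 genes rose for IFNg+CHX against CHX (28 and 13, 0.0239 expected, p = 3.7e-14), and without a block 0 (3 and 2). For IFNg+CHX against control, where the numbers do not pair the c-Jun null arrays, 1 gene, Irf8, was shared without a block (12 and 3, 0.00236 expected, exact p = 0.00236). Of the 104 genes raised by IFNg+CHX in WT, 11 were among the 11 raised by CHX and 22 among the 24 raised by IFNg. These pairs share arrays, so part of the excess may come from the shared arrays. Simulated unchanged groups gave 0 shared genes in 100 draws, and independent lists 0.0751 and 0.164, but neither value measures how much the shared arrays add.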

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

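Chosen only after the results were seen were the tests of exchanged labels, of CHX that did not act and of dynamic range for the c-Jun null arrays numbered 2, those of macrophages and of other line differences for the untreated genotypes, and that of cell composition for the replicate numbers. The effect of IFNg+CHX passed the test of a difference between the genotypes for Cxcl9 (-3.30, adjusted p = 0.0478), Zfp36 (-2.49, adjusted p = 0.0436) and Trim6 (-1.84, adjusted p = 0.0436). No gene passed this test after a median shift, without the dimmest 40%, over every probe set or with only the arrays compared. None passed with a block shared by both genotypes or without the 4 c-Jun null arrays numbered 2. Of 100 splits 11 gave 3 genes or more, a share that does not measure chance, as given below. Signal past the threshold also lay in data the comparisons leave out, the 2211 probe sets that name no gene or several. For IFNg+CHX against control these numbered 8 in WT and 1 in c-Jun null, for IFNg 2 and 1, for IFNg+CHX against CHX 1 and 1, and between the untreated genotypes 424 (194 higher and 230 lower in c-Jun null).

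The c-Jun null arrays numbered 2 showed genes raised by CHX the other way round. Over 416 genes past the threshold and higher with CHX in the 12 WT arrays, fitted with the replicate number as a term, CHX arrays exceeded the others by 0.47 to 0.53 on the log2 scale in the 4 c-Jun null pairs numbered 1 and 3, and by -0.52 and -0.53 in the pairs numbered 2. Against CHX that did not act in these cultures, the arrays labelled without CHX and numbered 2 lay 0.57 and 0.54 above those numbered 1 and 3, which differed by 0.06 and 0.16, and against array dynamic range the difference nearer 0 was -0.54 after quantile normalization. An exchange of CHX labels among the arrays numbered 2 may account for the pattern, since the difference nearer 0 was -0.52, a size within the range of the other pairs. No biological explanation was tested.

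Of 20 genes of the antiviral list, 16 were higher in untreated WT than in untreated c-Jun null arrays, with a median difference of 2.47 over the list (camera adjusted p = 0.171 with an estimated correlation). Macrophages in the WT cultures are argued against by a median difference of 0.17 over 11 macrophage markers, of which Cd14 passed the threshold, with Tyrobp at 5.41 and 5.24 and Cd68 at 7.18 and 7.28 in WT and c-Jun null controls. The scale of the arrays is argued against by a median of 2.54 after quantile normalization. The loss of c-Jun and other differences between the cell lines cannot be told apart, as the labels give 1 source per genotype and the 2 measured Y-linked genes differed as well.

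Arrays with the same replicate number deviated together within WT. Array dynamic range is argued against by a mean correlation of 0.72 (0.43 to 0.89) after quantile normalization, against 0.72 (0.35 to 0.90) before. Cultures that differed in cell composition stay open: both measured Y-linked genes lay lower in the 4 WT arrays numbered 2 than in the others, Kdm5d by a gap of 0.41 beside a larger SD of 0.38, but Eif2s3y by a gap of 0.21 beside a larger SD of 0.62. That SD pools the arrays numbered 1 and 3, which differed from each other. In each of the 4 treatments both genes were lowest in number 2 and highest in number 3. In the controls numbered 1 to 3, Eif2s3y was 6.75, 6.16 and 8.08. The design names no biological difference between replicate numbers, and apart from cell composition none was tested.

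Other splits of the same arrays were counted. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 12 and 3 genes for IFNg+CHX against control in WT and c-Jun null, 2 and 3 for IFNg, 3 for CHX in WT, 3 and 2 for IFNg+CHX against CHX and 3593 between the genotypes, and the highest other split gave 0 in each. For CHX in c-Jun null cells the real split gave 0 and the highest other 1. The 4 splits that part all pairs are too few as well: with the block the real splits gave 110, 26, 11 and 28 genes in WT for IFNg+CHX, IFNg, CHX and IFNg+CHX against CHX, and 10 and 13 in c-Jun null for IFNg and IFNg+CHX against CHX, with a highest other of 0. For the genotype difference in the IFNg+CHX effect, 11 of 100 splits gave 3 genes or more, the highest other 48. These splits regrouped the arrays inside each difference separately and without a block. They can therefore carry treatment effects and differences between replicate numbers, and the share does not measure chance. Chance was not excluded. For the differences with 0 genes, all 100 splits gave as many, which had to be so and tests nothing. The highest others were 9 (IFNg), 34 (CHX), 9 (IFNg under CHX), and 1175 and 767 (CHX difference in the IFNg effect in WT and c-Jun null). Which splits called so many genes was not examined, so the cause of these counts is not known.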

How the results depend on the processing

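The fits with a block within genotype, without the 4 c-Jun null arrays numbered 2, and with both were chosen after seeing the data. The genotype comparison had counts within 1.5 times of 3593 under each alternative fitted for it (2588 to 4997). A block within genotype could not be fitted for it, since it takes up the genotype difference. The plain t-test was run for IFNg+CHX against control only. Counts that moved by more follow, and unless said otherwise the cause was not tested. After quantile normalization c-Jun null gave 5 genes for IFNg+CHX against control and 4 for IFNg+CHX against CHX. The genotype difference in the IFNg+CHX effect gave 0 after a median shift, without the dimmest 40%, over every probe set, with only the arrays compared, with a block shared by both genotypes and without the 4 arrays. Over every probe set, counts were 24 and 6 (IFNg+CHX, WT and c-Jun null), 4 and 5 (IFNg), and 5 and 4 (IFNg+CHX against CHX), probe sets that name no gene or several included. With only the arrays compared, counts were 6 (WT IFNg+CHX), 0 (c-Jun null IFNg), and 1 and 1 (IFNg+CHX against CHX).

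With the replicate block shared by both genotypes, counts were 35 and 7 (IFNg+CHX), 8 and 5 (IFNg), 10 and 6 (IFNg+CHX against CHX) and 1 for the genotype difference in the IFNg effect under CHX. With the replicate block within genotype they were 110 and 15, 26 and 10, 11 (WT CHX), 28 and 13, and for the genotype differences 2 (IFNg), 11 (IFNg+CHX) and 1 (IFNg under CHX). Without the 4 arrays they were 34 and 8, 4 and 0, 15 and 4 (CHX), and 1 (c-Jun null IFNg+CHX against CHX). The WT differences themselves did not change, since these arrays enter the WT tests only through the shared spread. With both changes the counts were 278 and 97, 32 and 7, 118 and 75, 36 and 9, and for the genotype differences 1, 6 and 2. The plain t-test took each gene's spread from only the arrays compared. It gave 0 and 0 genes after adjustment for IFNg+CHX in WT and c-Jun null, and 440 and 227 unadjusted.

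Lists past camera fell with an estimated correlation to 5 and 2 (IFNg+CHX), 1 and 2 (IFNg), 2 and 0 (CHX), 1 (WT IFNg+CHX against CHX), 0 (genotype), and 0, 0 and 1 for the genotype differences in the IFNg, IFNg+CHX and CHX effects. With the block within genotype they were 5 and 10 (IFNg), 8 (c-Jun null CHX), 7 (c-Jun null IFNg+CHX against CHX), 5 and 4 for the genotype differences in the IFNg effect without and under CHX, and 1 for the CHX difference in WT. Without the 4 arrays 3 lists passed for the genotype difference in the IFNg+CHX effect. Genes shared at an adjusted p under 0.01 were 0 for IFNg+CHX between genotypes and 1 for IFNg without and with CHX in WT. With the block within genotype and an adjusted p under 0.05, shared genes were 11 (IFNg+CHX), 6 (IFNg) and 6 (IFNg+CHX against CHX) between genotypes, and 14 in WT and 9 in c-Jun null for IFNg without and with CHX. With the block and an adjusted p under 0.01 these were 6, 5, 2, 8 and 5.

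With each array left out in turn, counts ran from 6 to 20 and 1 to 4 (IFNg+CHX), 1 to 3 and 2 to 3 (IFNg), 1 to 3 and 0 to 0 (CHX), 1 to 6 and 2 to 3 (IFNg+CHX against CHX), 2922 to 3307 (genotype) and 0 to 4 (genotype difference in the IFNg+CHX effect). That difference gave 0 or 1 without any single array of its groups except the WT IFNg+CHX array numbered 1. The genotype difference in the IFNg effect under CHX gave 1 without the c-Jun null IFNg+CHX array numbered 3, and the CHX difference in c-Jun null 1 without the IFNg array numbered 3. For single genes named in the text, 140 values under an alternative newly passed the threshold, 137 no longer passed it, 2037 kept their side and none turned direction. In the comparisons whose numbers pair, every gene called without a block was also called with it within genotype. Signal over background was not used here, so which dim genes it limits is unknown.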

Other observations

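The test of histone genes was chosen after its result was seen, and that of Hox genes before. Hox genes, which encode transcription factors that mark position along the body axis, differed between the untreated lines. Of 32 measured, 16 passed the threshold (50%), against 3577 of 15192 other genes (23.55%; one-sided Fisher's exact test, p = 0.00103). In c-Jun null controls 6 were higher, led by Hoxc10 (3.13) and Hoxc13 (2.63), and 10 lower, led by Hoxa11 (-3.74), Hoxa9 (-2.58) and Hoxd13 (-2.33). A candidate explanation is a different positional origin of the embryonic cells; neighbouring Hox genes are not independent, and the labels give 1 source per genotype.

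Histone genes were among those higher with CHX in WT arrays. Of 21 measured, 18 lay above 0 (median 0.74), 12 passed the threshold over all 12 WT arrays in a fit with the replicate number as a term, and camera with an estimated correlation gave p = 5.5e-04. In the c-Jun null arrays numbered 1 and 3, fitted without that term, 0 passed the threshold and 18 of 21 lay above 0 (median 0.26). Camera with an estimated correlation gave 0.145 there. Whether histone transcripts rise in both lines stays open: the median lay on the side the hypothesis needs, and the rule set for rejecting it, a camera p that misses the threshold, was wrong because such a p does not show that the genes did not change. Histone genes have near-identical copies, so single values are uncertain.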
